A study of Mus musculus with 18 samples.

How the data were processed

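The measurements were bulk RNA sequencing of immune cells isolated from the brains of male wild-type mice. Per the labels, brain tissue was dissociated with papain and DNase, debris was removed on Percoll, neutrophils were depleted with Ly6G beads, and CD11b-positive cells (microglia and macrophages) were then selected with beads before SMART-Seq v4 PLUS libraries were made. There were 18 libraries in 6 groups of 3. Young mice (2 to 4 months) and aged mice (18 to 20 months) received bexarotene, an agonist of the retinoid X receptor (RXR), or vehicle. Aged mice of another pair of groups had a stroke by middle cerebral artery occlusion and then received either treatment. Per the labels, bexarotene was given at 5 mg/kg into the peritoneum, first at 24 hours after surgery and then daily for 2 days, the vehicle was 3% DMSO in saline, and cells were taken on day 3. Which surgery, if any, the mice without stroke had is not given in the sources used here. The labels call the samples biological replicates.

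The authors deposited a table of whole-number counts per gene for all 18 libraries, with no normalization, under Ensembl gene identifiers. Per the submitters' processing notes, the genome build was GRCm39, and Trimmomatic 0.40, STAR 2.7.10a, GATK and R 4.4.2 were used. The role of each tool, the annotation and the handling of strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies could not be told apart. The authors also deposited 4 tables of their own comparisons, each with a baseMean (the authors' mean of normalized counts), a log2 fold change with its error, a p-value and an adjusted p-value. The tool behind these deposited tables is not stated, and every gene listed in them has an adjusted p below 0.05. Gene symbols came from a reference annotation of an earlier build (GENCODE M21, GRCm38), which was used for names and for the order of neighbouring genes and not for coordinates. It named 52029 of 57010 genes, and the deposited tables raised this to 52033. The 4977 genes left without a symbol held 0.326% of the counts and stayed in the tests under their identifiers. Every column of per-sample values was used.

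Library totals ran from 7582511 to 11852638 counts without stroke and from 16206144 to 29359943 with stroke. A floor of 3 counts corresponded to 0.396 CPM (counts scaled by the library total) in the shallowest library. This floor covers counting error only, because reads without molecular identifiers are not independent molecules. Intervals of a fold change come from the model and carry the variation between libraries, and bootstrap intervals are over genes. No 2 libraries of a group differed by as little as sampling noise, since the chi-square per degree of freedom between replicates was 6.19 to 41.8.

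Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes with low counts were removed with filterByExpr, which left 15528 genes, libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions was fitted to all 18 libraries (12 residual degrees of freedom, square root of the common dispersion 0.195). The comparisons were aged against young vehicle, bexarotene against vehicle in each of the 3 settings, stroke against no stroke in aged vehicle mice, and the differences of the bexarotene effect between aged and young mice and between aged mice with and without stroke. A gene was called changed at an adjusted p under 0.05 with Benjamini-Hochberg (BH) adjustment over all genes tested, and all calls and adjusted p-values of single genes come from this edgeR quasi-likelihood test unless another tool or setting is named. Fold changes are log2 values with a standard error (SE) derived from the F statistic, each from 3 libraries per group, and levels are mean CPM. Unlike the floor, CPM of genes are scaled by the library total over the genes tested times the TMM factor (0.937 to 1.05). In all, 41 lists of genes (markers of brain and blood cell types, signs of RNA handling, microglial states, nuclear receptor targets, metabolism, proliferation and tissue repair) were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives described as planned. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with BH adjustment over the 41 lists, and single members were also adjusted over the list alone.

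Genes were named by a fixed rule. It took, per comparison, the 8 called genes of each sign with the largest fold change, a mean of at least 10 CPM in the higher group and no overlap between groups. It added up to 4 members with the lowest p of each list that passed camera or had at least 3 called members, and a few genes fixed in advance for age, bexarotene and stroke. For the differences of the bexarotene effect it took 3 called genes of each sign, and where fewer than 4 genes were called, the 5 with the lowest p as values without a call. Predicted and unnamed genes were passed over, and a few genes that the rule takes are not reported here. By a choice made after seeing the data, single genes with a mean under 1 CPM in a group compared are given in CPM without a fold.

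The alternatives planned were RLE scaling, no filter, DESeq2 1.42.0, limma voom with quality weights, a fit to only the groups compared, the replicate number as a block, and leaving out each library in turn. A further 3 were chosen after seeing the data: a choroid plexus score as covariate, choroid plexus and neutrophil scores as 2 covariates, and leaving out the libraries numbered 1 together. The replicate numbers come from the labels, which do not say what they mark. Same-numbered libraries were taken as paired where the correlation of their deviations from the group means was over 0.1 for every number. This held for young bexarotene against young vehicle (0.26, 0.28 and 0.14) and for no other comparison, so blocked values are given for that one where the block changes a call.

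The code was tested on simulated counts, a single draw per comparison, with 200 genes changed by known folds. At 2-fold and 4-fold, edgeR recovered 47.8% and 74.2% of the changed genes for age, 61.2% and 63.6% for bexarotene in young mice, 55.2% and 75.8% in aged mice, and 56.7% and 72.7% after stroke. It recovered 52.2% and 84.8% for stroke itself, 38.8% and 65.2% for the difference between aged and young mice, and 31.3% and 69.7% for the difference between aged mice with and without stroke. The aged and young vehicle comparison shares its aged vehicle libraries with the aged bexarotene comparison, so their overlap was set against 20 simulations without a bexarotene effect in aged mice.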

Results

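RNA was measured in CD11b-selected brain cells of 6 groups of male mice, 3 libraries each: young vehicle, young bexarotene, aged vehicle, aged bexarotene, aged stroke vehicle and aged stroke bexarotene. Total counts per library were 7582511 to 11378554 in young vehicle and 8446098 to 10173924 in young bexarotene. They were 10246885 to 10656746 in aged vehicle and 9346466 to 11852638 in aged bexarotene. With stroke they were higher, 16402880 to 21009478 in vehicle and 16206144 to 29359943 in bexarotene libraries. In every group the homeostatic microglial gene P2ry12 was abundant, with 12804 CPM in young vehicle, 10190 CPM in aged vehicle and 2505 CPM in aged stroke vehicle. The first principal component held 59.9% of the variance and separated the 6 stroke libraries (88.7 to 114) from the 12 others (-68.4 to -37.4).

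**Figure D1:**
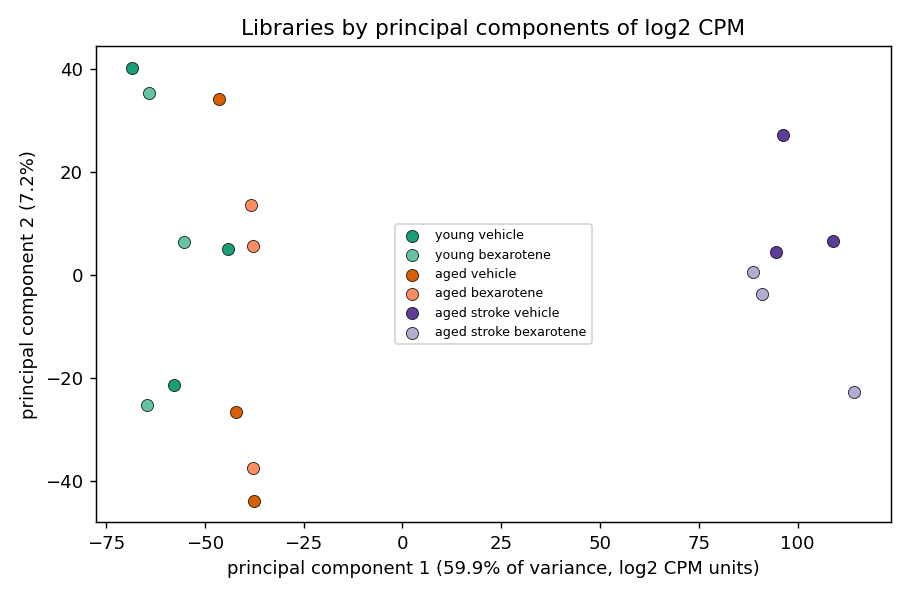
The 18 libraries on the first 2 principal components (axes in component units, with the share of variance of each), one point per library, coloured by group. The 6 stroke libraries sit between 88.7 and 114 on the first component and the 12 others between -68.4 and -37.4.

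The series title raises the question of whether RXR activation reverses changes that come with age. Aged vehicle cells held more transcripts of interferon-induced genes than young vehicle cells. Of 18 interferon response genes, 12 rose (18 when adjusted over the list alone) and the median log2 fold change was 1.42 (camera adjusted p = 7.81e-48 with BH, adjusted p = 0.0165 with an estimated correlation). Usp18, which removes the ubiquitin-like modifier ISG15 from proteins, rose from 8.53 to 29.0 CPM (log2 fold change 1.75 ± 0.20 SE, n = 3 libraries per group). The antiviral Oas1a rose by 1.61 ± 0.18 and Oasl2 by 1.51 ± 0.20, and Rtp4 rose by 1.19 ± 0.16.

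Genes of disease-associated microglia rose with age as well, 9 of 21 members (16 when adjusted over the list alone), with a median of 0.93 (camera adjusted p = 1.29e-26 with BH, adjusted p = 0.0333 with an estimated correlation). Spp1, which encodes the secreted protein osteopontin, went from 8.78 to 313 CPM (5.19 ± 0.63), the beta-glucan receptor Clec7a from 25.2 to 130 CPM (2.36 ± 0.30) and the receptor kinase Axl from 42.8 to 171 CPM (2.00 ± 0.26). The protease inhibitor Cst7 rose by 3.17 ± 0.47 and the tetraspanin Cd63 by 0.92 ± 0.14. Apoe, the lipid carrier, averaged 1919 CPM in young and 3648 CPM in aged vehicle cells and missed the threshold (0.93 ± 0.23, adjusted p = 0.0558, edgeR quasi-likelihood with BH). Apoe was called higher by DESeq2, by limma voom, with the choroid plexus covariate and without the libraries numbered 1, the last pair of settings chosen after seeing the data. Fitted to the 2 groups alone, the calls of Spp1, Clec7a, Axl, Cst7 and Mmp12 were lost with the same sign of change.

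Of 11 genes of MHC class I presentation, 5 rose (7 when adjusted over the list alone), with a median of 0.35 (camera adjusted p = 6.58e-12 with BH, adjusted p = 0.0248 with an estimated correlation). They included the class I chains H2-D1 (1.14 ± 0.15, 697 to 1533 CPM) and H2-K1 (0.91 ± 0.14), their partner B2m (0.79 ± 0.14) and the transcriptional activator Nlrc5 (1.42 ± 0.25). Class I genes are near-identical copies of each other, so the division of reads among them is uncertain. Markers of border-associated macrophages, which live at the brain's surfaces and vessels, fell. The lectin Clec10a (-1.30 ± 0.23), the reductase Cbr2 (-0.83 ± 0.17) and the chemokine Pf4 (-0.98 ± 0.21) were the 3 called of 13 members (5 when adjusted over the list alone), with a median of -0.58 (camera adjusted p = 2.65e-05 with BH, adjusted p = 0.0333 with an estimated correlation). Without the libraries numbered 1, a setting chosen after seeing the data that leaves fewer samples, these 3 and B2m and Nlrc5 lost their calls. Homeostatic microglial genes were lower in 15 of 16 cases, none was called by edgeR (2 when adjusted over the list alone), and the median was -0.22 (camera adjusted p = 9.24e-04 with BH, adjusted p = 0.467 with an estimated correlation). Limma voom called Csf1r, Cx3cr1 and Mef2c lower, while P2ry12 (-0.33 ± 0.16) and the microglial marker Tmem119 (-0.14 ± 0.13) were not called.

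Beyond these lists, and among genes with at least 10 CPM in the higher group and no overlap between groups, the largest rises with age were in the chemokine Cxcl13 (0.0582 to 11.0 CPM), the macrophage elastase Mmp12 (4.50 ± 0.58, 1.86 to 42.9 CPM), and the inhibitory receptor Pdcd1 (3.35 ± 0.29, 1.82 to 18.5 CPM). Rises followed in the potassium channel Kcnj12 (3.11 ± 0.42), the sulfotransferase Chst2 (2.91 ± 0.30) and Ildr2 (2.72 ± 0.26). Cd22, an inhibitory sialic acid receptor first known from B cells, rose from 9.22 to 41.0 CPM (2.15 ± 0.17). The chemokines Ccl3 (1.82 ± 0.27) and Ccl4 (1.59 ± 0.24) rose, while the cytokines Tnf (0.79 ± 0.29) and Il1b (-1.11 ± 0.65), the lectin Lgals3 (1.61 ± 0.58) and the cell cycle inhibitor Cdkn1a (0.82 ± 0.21) were not called by edgeR. DESeq2 and limma voom called Cdkn1a, and limma voom did not call Cxcl13. Without the libraries numbered 1 Cdkn1a was called, and Ccl3 and Cnbd2 lost their calls. By the same rule the largest falls were in the kinase subunit Camk2b (12.2 to 0.516 CPM), the receptor Gpr165 (-2.77 ± 0.40, 273 to 40.1 CPM), and Rgs7bp (-2.64 ± 0.28). The endosomal protein Wdfy1 (-1.93 ± 0.13, 115 to 30.2 CPM), the endothelin receptor Ednrb (-1.80 ± 0.22), Cdk5rap1 (-1.67 ± 0.41), Nbea (-1.59 ± 0.28) and Cnbd2 (-1.44 ± 0.23) fell as well.

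Other lists passed camera in aged cells at the preset correlation alone. Of 32 ribosomal protein genes, 6 rose (27 when adjusted over the list alone), among them Rpl22 (0.80 ± 0.13) and Rpl37 (0.66 ± 0.11), with a median of 0.40 (camera adjusted p = 2.67e-25 with BH, adjusted p = 0.111 with an estimated correlation). DESeq2 called 19 and limma voom 12 of them, a fit to the 2 groups alone 2, without Rpl22, and the fit without the libraries numbered 1 only Rpl22. The 7 genes of MHC class II presentation had a median of 1.18 with none called by edgeR (6 when adjusted over the list alone; camera adjusted p = 2.16e-06 with BH, adjusted p = 0.185 with an estimated correlation). Cd74, the invariant chain, was at 249 and 613 CPM (1.30 ± 0.40). DESeq2 called Cd74, H2-Aa and H2-Ab1 higher, and edgeR called H2-Ab1 when fitted to the 2 groups alone. Glycolysis genes had a median of 0.40 with 0 of 15 called by edgeR (9 when adjusted over the list alone; camera adjusted p = 3.92e-07 with BH, adjusted p = 0.185 with an estimated correlation). DESeq2 and limma voom called Aldoa, Pfkfb3 and Pfkl higher, and edgeR called Aldoa or Pfkfb3 under some other settings. For matrix remodelling genes the median (-0.09) was below 0 while the mean (0.87) and the test were above 0 (camera adjusted p = 0.0108 with BH, adjusted p = 0.425 with an estimated correlation), with Spp1, Mmp12 and the crosslinking enzyme Lox (0.839 to 7.74 CPM) called of 13 (3 when adjusted over the list alone). All 12 neutrophil markers were lower in aged vehicle cells, none called (0 when adjusted over the list alone), with a median of -1.22 (camera adjusted p = 0.0126 with BH, adjusted p = 0.544 with an estimated correlation).

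In total 264 of 15528 genes changed with age, 196 higher and 68 lower, 150 of them over 2-fold, by edgeR's quasi-likelihood test with BH adjustment. At an unadjusted p under 0.05 there were 2034 genes, where chance gives 776. The groups did not overlap in 263 of the called genes, and in 18.4% of all genes against 10% by chance. The count was 126 without young vehicle library 1, 174 without young vehicle library 2, 159 without aged vehicle library 2 and 150 without aged vehicle library 3. Cbr2, Pf4, Lox, Cdk5rap1, Rpl13, Ndufa1 and Asns each lost their call without at least 1 library, and limma voom called neither Ndufa1 nor Asns.

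Bexarotene in young mice raised genes of cholesterol export and other RXR targets. Abcg1, which exports cholesterol and is induced by the LXR-RXR receptor pair, rose from 103 to 486 CPM (log2 fold change 2.23 ± 0.14 SE, n = 3 libraries per group, adjusted p = 3.21e-08, edgeR quasi-likelihood with BH). Its relative Abca1 rose from 465 to 1005 CPM (1.11 ± 0.14), the small GTPase Arl4c by 0.82 ± 0.15, and Tgm2, a transglutaminase induced by retinoic acid, from 77.5 to 344 CPM (2.15 ± 0.27). Without the libraries numbered 1, a setting chosen after seeing the data, Tgm2 lost its call (2.22, adjusted p = 0.134, 1.40e-10 to 0.134 over its alternatives, edgeR with BH). Eepd1, known as an LXR target in macrophages, rose from 26.5 to 158 CPM (2.58 ± 0.27). Cpt1a, which brings fatty acids into mitochondria, rose by 0.76 ± 0.14.

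Of 12 LXR-RXR targets, 3 rose (4 when adjusted over the list alone, which also put 1 lower), with a median of 0.19 (camera adjusted p = 8.53e-11 with BH, adjusted p = 0.00110 with an estimated correlation). The 5 RAR-RXR targets had a median of 0.38 with Tgm2 called (2 when adjusted over the list alone; camera adjusted p = 1.59e-05 with BH, adjusted p = 0.0173 with an estimated correlation). All 16 PPAR-RXR targets were higher, with Cpt1a called (1 when adjusted over the list alone) and a median of 0.27 (camera adjusted p = 6.52e-06 with BH, adjusted p = 0.0805 with an estimated correlation). The ubiquitin ligase Mylip (0.67 ± 0.16), the lipase inhibitor Angptl4 (0.678 to 2.42 CPM), the lipogenic regulator Srebf1 (0.10 ± 0.12) and Apoe (0.31 ± 0.23) were not called. Nor were the scavenger receptor Cd36 (0.28 ± 0.16), the kinase Pdk4 (0.662 to 1.13 CPM) and the receptor gene Rxra (-0.09 ± 0.11). DESeq2 and limma voom called Mylip, and in the RAR-RXR list Dhrs3, higher.

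Further rises in young mice included the growth factor Hbegf (2.54 ± 0.35), the calcineurin regulator Rcan1 (2.48 ± 0.47), the kinase Camkk1 (2.11 ± 0.26) and the ephrin receptor Epha2 (1.71 ± 0.17). The largest falls by the same rule were in Osbpl3 (-1.13 ± 0.24), Btbd3 (-0.99 ± 0.18), and the transcriptional repressor Prdm1 (-0.99 ± 0.21). The oxysterol receptor Gpr183 (-0.90 ± 0.14, 417 to 224 CPM), Dynll1 (-0.85 ± 0.17), Smcr8 (-0.72 ± 0.15), the semaphorin receptor Nrp2 (-0.66 ± 0.14) and Ccdc82 (-0.61 ± 0.13) fell too. With the replicate block, Rcan1 (adjusted p = 0.0554, 1.53e-05 to 0.284 over its alternatives), Nrp2 (0.0580, 0.00302 to 0.528) and Prdm1 (0.0647, 0.00102 to 0.504) missed the threshold by edgeR with BH. With the block the threshold was also passed by the microglial transcription factor Mef2c (-0.55, adjusted p = 0.0373, 0.00330 to 0.457 over its alternatives) and the cytokine Il6 (1.18, adjusted p = 0.0459, 0.00618 to 0.283), again by edgeR with BH. Other tools and the choroid plexus covariate also called one or the other.

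Other lists in young mice passed camera at the preset correlation alone. Interferon response genes were higher in 17 of 18 cases, none called (0 when adjusted over the list alone), with a median of 0.33 (camera adjusted p = 3.16e-04 with BH, adjusted p = 0.827 with an estimated correlation). All 11 heat shock genes were lower, none called by edgeR and Dnajb1 called by DESeq2 (0 when adjusted over the list alone), with a median of -0.55 (camera adjusted p = 9.11e-06 with BH, adjusted p = 0.525 with an estimated correlation). Markers of infiltrating monocytes and macrophages were lower in 14 of 16 cases, none called (0 when adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.0149 with BH, adjusted p = 0.925 with an estimated correlation). The inflammasome sensor Nlrp3 rose (0.57 ± 0.11) as the one called by edgeR of 17 inflammatory genes (3 higher and 4 lower when adjusted over the list alone), whose median was -0.56 (camera adjusted p = 0.0120 with BH, adjusted p = 0.418 with an estimated correlation). DESeq2 also called Il6 higher and Tnf, Il1b and Ptgs2 lower, and with the choroid plexus covariate, chosen after seeing the data, edgeR called Il6 and Ptgs2. For matrix remodelling genes, none called (0 when adjusted over the list alone), the median was -0.51 (camera adjusted p = 0.0341 with BH, adjusted p = 0.747 with an estimated correlation). That list missed the threshold with the replicate block (adjusted p = 0.0532, 0.0390 to 0.747 over its alternatives). Neutrophil S100a8 was at 69.0, 138 and 338 CPM in the young vehicle libraries and 53.3, 74.2 and 264 CPM in the young bexarotene libraries.

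In total 79 genes changed with bexarotene in young mice, 65 higher and 14 lower, by edgeR's quasi-likelihood test with BH adjustment, and the groups did not overlap in any of them (13.1% of all genes against 10% by chance). The count was 30, 33 and 27 without young vehicle library 1, 2 and 3, and 36 and 38 without young bexarotene library 1 and 3. Rcan1, Cpt1a, Arl4c, Nlrp3, Osbpl3, Btbd3, Prdm1, Dynll1, Smcr8, Nrp2 and Ccdc82 each lost their call without at least 1 library. All of these except Arl4c also lost it without the libraries numbered 1, Gpr183 lost it in a fit to the 2 groups alone, and limma voom did not call Nrp2.

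In aged mice without stroke, bexarotene raised several of the same genes. Abcg1 rose from 95.8 to 450 CPM (2.23 ± 0.14 SE, n = 3 libraries per group, adjusted p = 3.18e-08, edgeR quasi-likelihood with BH). Abca1 rose from 459 to 889 CPM (0.96 ± 0.14), Tgm2 from 83.0 to 367 CPM (2.14 ± 0.27) and Eepd1 from 20.5 to 115 CPM (2.49 ± 0.27). Tgm2 again lost its call without the libraries numbered 1 (2.15, adjusted p = 0.119, 2.10e-10 to 0.119 over its alternatives, edgeR with BH). Camkk1 (1.91 ± 0.25), Tcim (1.78 ± 0.33), the NAD-consuming enzyme Cd38 (1.66 ± 0.27), Mmd (1.45 ± 0.17), the semaphorin Sema4a (1.34 ± 0.22) and Cpt1a (0.70 ± 0.14) also rose. The 3 genes that fell were Chst2 (-1.28 ± 0.26), the stress-induced regulator Nupr1 (-0.67 ± 0.13) and Tent5c (-0.55 ± 0.11). Mylip (0.47 ± 0.16), Angptl4 (0.285 to 1.23 CPM), Srebf1 (0.30 ± 0.12), Apoe (-0.26 ± 0.23), Cd36 (0.53 ± 0.16), Pdk4 (0.188 to 1.14 CPM) and Rxra (-0.36 ± 0.11) were not called. DESeq2 called Arl4c higher and Scd2 lower.

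Of the 12 LXR-RXR targets, 2 rose (6 when adjusted over the list alone, which also put 1 lower), with a median of 0.22 (camera adjusted p = 8.98e-11 with BH, adjusted p = 0.00113 with an estimated correlation). Among the 5 RAR-RXR targets Tgm2 was called (2 when adjusted over the list alone), with a median of 0.28 (camera adjusted p = 8.28e-06 with BH, adjusted p = 0.0132 with an estimated correlation). For the 16 PPAR-RXR targets Cpt1a was called (3 when adjusted over the list alone) and the median was 0.17 (camera adjusted p = 1.73e-05 with BH, adjusted p = 0.101 with an estimated correlation). All 11 heat shock genes were lower, none called (7 when adjusted over the list alone), with a median of -0.76 (camera adjusted p = 9.84e-10 with BH, adjusted p = 0.324 with an estimated correlation). The libraries overlapped: Hspa1b, which shares reads with the near-identical Hspa1a, was at 29.5, 142 and 377 CPM in aged vehicle and at 161, 17.0 and 18.3 CPM in aged bexarotene.

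Some lists of other cells and of handling passed camera in this comparison at the preset correlation alone. Neutrophil markers were higher in 11 of 12 cases with a median of 1.65, none called by edgeR and Mmp9 called by DESeq2 (1 when adjusted over the list alone; camera adjusted p = 7.85e-07 with BH, adjusted p = 0.541 with an estimated correlation). S100a8 was at 104, 89.6 and 46.8 CPM in aged vehicle and at 247, 146 and 386 CPM in aged bexarotene libraries, although Ly6G beads had been used to deplete neutrophils. Markers of infiltrating monocytes and macrophages, none called (0 when adjusted over the list alone), had a median of 0.49 (camera adjusted p = 0.00549 with BH, adjusted p = 0.641 with an estimated correlation). Immediate early genes of dissociation, likewise none called except Dusp1 without the libraries numbered 1 (0 when adjusted over the list alone), had a median of 0.41 (camera adjusted p = 0.00748 with BH, adjusted p = 0.613 with an estimated correlation). Oligodendrocyte markers went the other way, lower in 8 of 9 cases with a median of -0.64, none called (0 when adjusted over the list alone; camera adjusted p = 0.0177 with BH, adjusted p = 0.560 with an estimated correlation).

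In total 40 genes changed with bexarotene in aged mice, 37 higher and 3 lower, by edgeR's quasi-likelihood test with BH adjustment, and the groups did not overlap in any of them (11.8% of all genes against 10% by chance). With RLE scaling the count was 24, and with choroid plexus and neutrophil scores as covariates, chosen after seeing the data, it was 9. The neutrophil score was 3.86 to 4.78 in aged vehicle and 5.34 to 6.59 in aged bexarotene libraries. Because it separates the groups, the drop cannot tell RNA of other cells from lost power. Left out in turn, aged vehicle library 1, 2 and 3 gave 18, 12 and 9 genes and aged bexarotene library 2 and 3 gave 16 and 10. Abca1 lost its call without aged vehicle library 3 and with both covariates, where its fold change was 0.82 against 0.96 (adjusted p = 0.0606, 2.81e-08 to 0.0606 over its alternatives, edgeR with BH). Cpt1a, Sema4a, Cd38, Tcim, Nupr1, Chst2 and Tent5c lost theirs without at least 1 library, all but Chst2 also lost them without the libraries numbered 1, and limma voom did not call Tcim.

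**Figure D2:**
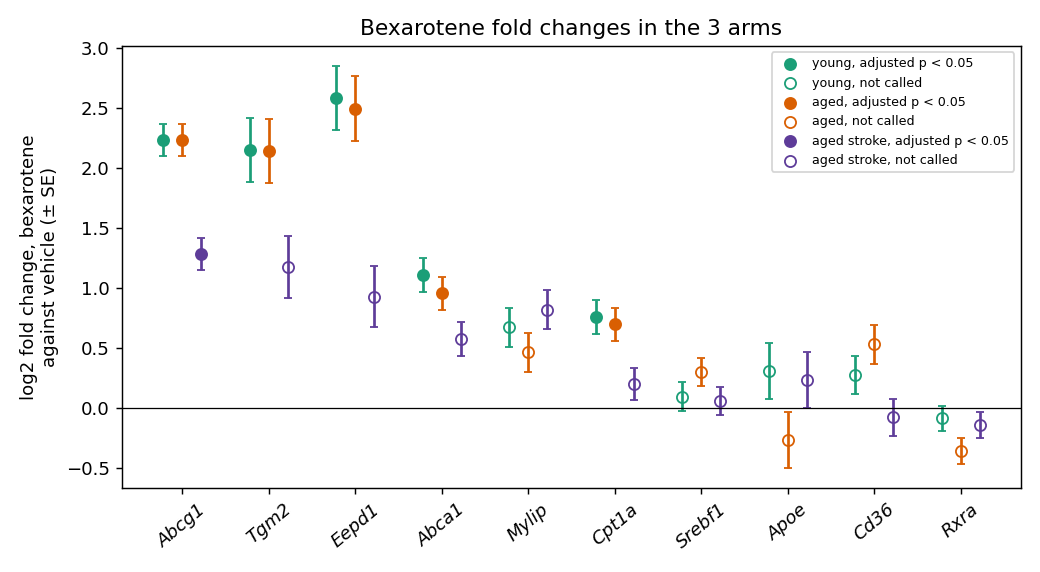
Log2 fold change of 10 genes with bexarotene against vehicle in young, aged and aged stroke mice, with bars for the SE (n = 3 libraries per group) and filled points for genes called changed. Abcg1 was called in all 3 settings, at 2.23, 2.23 and 1.28.

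After stroke, bexarotene changed 9 genes, 8 higher and 1 lower. Abcg1 rose from 126 to 308 CPM (1.28 ± 0.13 SE, n = 3 libraries per group, adjusted p = 1.57e-04, edgeR quasi-likelihood with BH). The transcriptional repressor Hic1, a retinoic acid target, rose from 4.90 to 26.8 CPM (2.44 ± 0.44), and Epha2 rose by 0.97 ± 0.16. Mmd (0.95 ± 0.16), the ganglioside synthase St3gal5 (0.76 ± 0.12), Engase (0.71 ± 0.13) and the sterol-responsive ubiquitin ligase Rnf145 (0.55 ± 0.10) rose. Frmd6 fell from 6.63 to 2.25 CPM (-1.55 ± 0.22), a gene outside the naming rule that was chosen after its values were seen. Abca1 (0.58 ± 0.14), Tgm2 (1.17 ± 0.25), Mylip (0.82 ± 0.16), Angptl4 (1.85 ± 0.45), Srebf1 (0.06 ± 0.12), Apoe (0.23 ± 0.23), Cd36 (-0.07 ± 0.15), Pdk4 (0.933 to 0.942 CPM) and Rxra (-0.14 ± 0.11) were not called by edgeR. DESeq2 called Abca1, Tgm2, Mylip, Angptl4 and Dhrs3 higher after stroke, and limma voom called Angptl4.

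The 12 LXR-RXR targets had a median of 0.14 with Abcg1 called (4 when adjusted over the list alone; camera adjusted p = 5.00e-07 with BH, adjusted p = 0.00705 with an estimated correlation). The 5 RAR-RXR targets had a median of 0.46 and a mean of 0.08 with Hic1 called (3 when adjusted over the list alone; camera adjusted p = 9.40e-05 with BH, adjusted p = 0.0341 with an estimated correlation). Interferon response genes were lower in 17 of 18 cases, none called (3 when adjusted over the list alone), with a median of -0.31 (camera adjusted p = 6.03e-07 with BH, adjusted p = 0.600 with an estimated correlation). Border-associated macrophage markers were lower in 12 of 13 cases, none called (2 when adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.00134 with BH, adjusted p = 0.147 with an estimated correlation).

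Choroid plexus transcripts also varied between these libraries, within groups as well as between them. The 6 ependymal and choroid plexus markers were all lower with bexarotene after stroke, none called (0 when adjusted over the list alone), with a median of -1.90 (camera adjusted p = 0.00134 with BH, adjusted p = 0.600 with an estimated correlation). Ttr, the choroid plexus product transthyretin, was at 1988, 594 and 701 CPM in aged stroke vehicle and at 398, 90.7 and 478 CPM in aged stroke bexarotene libraries. S100a8 was at 196, 795 and 350 CPM and at 155, 245 and 1112 CPM in the same libraries.

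**Figure D3:**
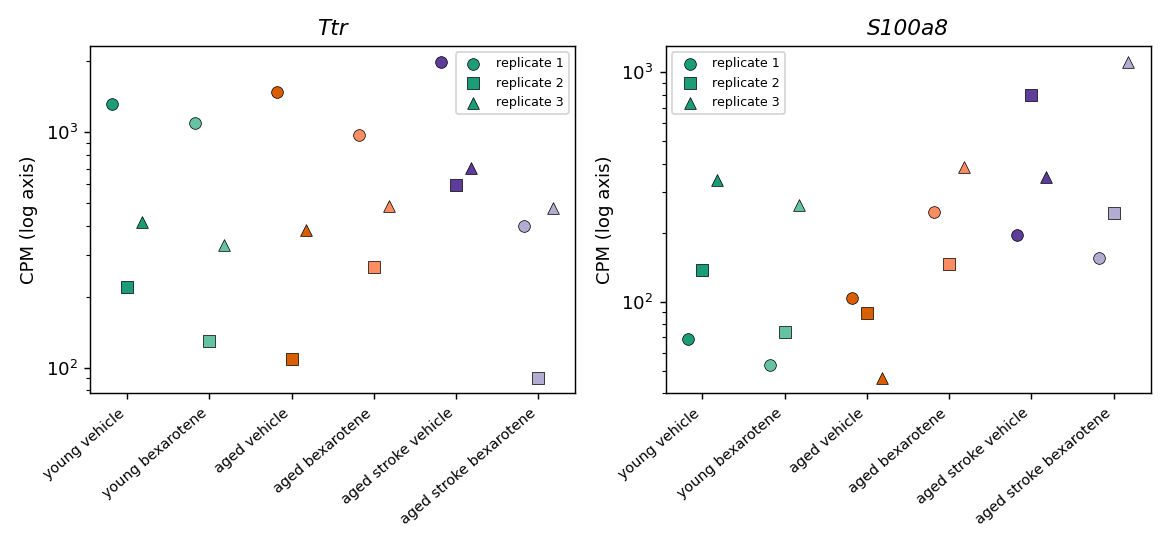
CPM on a log axis of Ttr, a choroid plexus transcript, and S100a8, a neutrophil transcript, in each of the 18 libraries by group, with the marker shape giving the replicate number. Ttr reached 1988 CPM in aged stroke vehicle library 1, and S100a8 reached 1112 CPM in aged stroke bexarotene library 3.

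The count of 9 by edgeR's quasi-likelihood test with BH adjustment stood beside 988 genes at an unadjusted p under 0.05, where chance gives 776. The groups did not overlap in 11.3% of all genes against 10% by chance. It was 4 and 1 without aged stroke vehicle library 1 and 2, and 5, 17 and 2 without aged stroke bexarotene library 1, 2 and 3. Abcg1 kept its call in every alternative, and Hic1, Epha2, Mmd, St3gal5, Engase and Rnf145 lost theirs without at least 1 library and without the libraries numbered 1. Hic1 also lost its call with RLE scaling, with the choroid plexus covariate and with both covariates. Frmd6 lost its call without aged stroke vehicle library 2, without aged stroke bexarotene library 3 and without the libraries numbered 1, where 0 genes were called lower. It also lost its call in a fit to these groups alone, and limma voom called neither Mmd nor Engase.

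Across the 3 bexarotene comparisons, 6 genes rose in each, among them Abcg1 (2.23, 2.23 and 1.28 in young, aged and aged stroke mice), Epha2 (1.71, 1.19 and 0.97), Mmd (1.40, 1.45 and 0.95), St3gal5 (1.18, 1.22 and 0.76) and Rnf145 (0.71, 0.61 and 0.55). Young and aged mice, which share no libraries, had 26 raised genes in common where independent lists give 0.155, and 78 of the 79 genes called in young mice had the same sign in aged mice. Young and aged stroke mice had 6 raised genes in common where independent lists give 0.0335, with the same sign in 74 of 79. Across all genes the log2 fold changes correlated at r = 0.187 and r = 0.239 for these pairs, over genes that are not independent replicates.

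By edgeR no gene passed the test of the difference of the bexarotene effect between aged and young mice. The count of 0 by edgeR with BH stood beside 456 genes at an unadjusted p under 0.05, where chance gives 776. DESeq2 called 5 and limma voom 0. The lowest p-values belonged to Tnfsf14 (1.08 to 0.502 CPM in young and 0.223 to 2.13 CPM in aged mice), Padi4 (2.81 ± 0.62), Fam107b (0.67 ± 0.15), Fblim1 (-0.95 ± 0.23) and Stx11 (3.03 ± 0.72), given as values without a call by edgeR. DESeq2 called Tnfsf14, Padi4, Fam107b and Stx11. The difference between aged mice with and without stroke gave 0 genes by edgeR with BH, 9 by DESeq2 and 0 by limma voom. At an unadjusted p under 0.05 it gave 638 genes, again fewer than the 776 of chance. Abcg1 differed by -0.95 ± 0.18 (adjusted p = 0.535, edgeR quasi-likelihood with BH), Frmd6 by -1.53 ± 0.30 and Fam43a by -1.49 ± 0.34, none called by edgeR, and Tnfsf14, not called either, was at 11.9 and 8.54 CPM after stroke. DESeq2 called Abcg1, Frmd6, Tnfsf14 and Hecw2 for this difference. Hecw2, also among the lowest p-values, had no counts in aged vehicle and 0.691 CPM in aged bexarotene. Leaving out young vehicle library 1 gave 1 gene for the first difference.

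Genes that changed with age and moved back with bexarotene in aged mice numbered 2. Chst2 rose with age (2.91 ± 0.30) and fell with bexarotene (-1.28 ± 0.26), and Camk2b fell with age (12.2 to 0.516 CPM) and rose with bexarotene (to 3.42 CPM), and 0 genes were called in the same direction in both. Both comparisons use the aged vehicle libraries, and simulations without a bexarotene effect gave 0.1 opposite genes on average (0 to 1). They left little room for such genes, since they called 0.15 bexarotene genes on average against 40 observed. Independent lists give 0.0379 and 0.162 for the 2 directions. Of the 264 age-called genes, 73.9% had the opposite sign with bexarotene, against 70.2% (67.3% to 73.0%) in the simulations. That share is over another set of genes, because the simulations called 809 to 940 age genes. The correlation of the fold changes over all genes was -0.396 against -0.304 (-0.340 to -0.272), and the covariance was -0.142 against -0.110. The simulated age fold changes were drawn around fitted means that already held noise. That widens them and pulls the simulated correlation towards 0, so part of the gap in r is built in. Against the aged stroke comparison, which shares no library with the age comparison, 43.2% of the age-called genes had the opposite sign, r was 0.0485, 0 genes were opposite and 1 was called in the same direction. With 3 libraries the controls could not be split, so how much of the opposite movement comes from the shared controls is not settled. The count of 2 became 4 without aged vehicle library 1, 1 without aged vehicle library 2 or aged bexarotene library 1, and 0 without young vehicle library 1, 2 or 3, aged vehicle library 3 or aged bexarotene library 2 or 3. Under other settings it was 1 with RLE scaling or a fit to the groups compared, 3 by limma voom and 10 by DESeq2. It was 111 without a filter and 0 with both covariates.

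Stroke changed 7497 of the 15528 genes in aged vehicle mice, 4216 higher and 3281 lower, by edgeR's quasi-likelihood test with BH adjustment. The groups did not overlap in 56.1% of all genes against 10% by chance. Microglial identity genes fell in this bulk RNA of CD11b-selected cells. A change within cells cannot be told there from a changed mix of microglia and incoming macrophages. This limit holds for all stroke results given here. Of 16 homeostatic genes, 14 fell, with a median of -1.42 (camera adjusted p = 1.41e-14 with BH, adjusted p = 0.126 with an estimated correlation). P2ry12 fell from 10190 to 2505 CPM (-2.02 ± 0.16 SE, n = 3 libraries per group), Tmem119 from 5292 to 1778 CPM (-1.57 ± 0.13), the sugar transporter Slc2a5 by 1.82 ± 0.14 and the selectin ligand Selplg by 1.53 ± 0.13. The receptors Trem2 (-0.76 ± 0.11) and Mertk (-1.17 ± 0.13), which take part in clearing debris, also fell.

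All 16 markers of infiltrating monocytes and macrophages rose, with a median of 5.22 (camera adjusted p = 5.94e-13 with BH, adjusted p = 0.163 with an estimated correlation). The monocyte chemokine receptor Ccr2 went from 37.6 to 787 CPM (4.39 ± 0.50), fibronectin Fn1 from 8.96 to 1216 CPM (7.08 ± 0.64) and Thbs1 from 20.8 to 2380 CPM (6.83 ± 0.56). Arginase Arg1 went from 0.412 to 300 CPM. All 20 cell cycle genes rose, with a median of 4.22 (camera adjusted p = 1.21e-33 with BH, adjusted p = 0.0337 with an estimated correlation), among them Birc5 (4.98 ± 0.23), the cyclin Ccna2 (5.00 ± 0.25) and the kinase Cdk1 (4.04 ± 0.19). All 18 interferon response genes rose, with a median of 3.71 (camera adjusted p = 2.02e-34 with BH, adjusted p = 0.0337 with an estimated correlation), including Oasl2 (3.34 ± 0.20) and Oas1a (3.04 ± 0.17). Adjusted over the list alone, the counts of these 4 lists were 14, 16, 20 and 18.

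Disease-associated genes rose in 13 of 21 cases and fell in 1 (Trem2), with a median of 0.90 (camera adjusted p = 0.00829 with BH, adjusted p = 0.617 with an estimated correlation). Spp1 went from 313 to 7488 CPM (4.58 ± 0.57) and Lgals3 from 39.9 to 547 CPM (3.78 ± 0.57). Inflammatory genes rose in 11 of 17 cases and fell in 4, with a median of 2.28 (camera adjusted p = 0.00941 with BH, adjusted p = 0.313 with an estimated correlation). The chemokine Ccl2 rose by 4.64 ± 0.32, Il1b by 4.22 ± 0.69 and Tnf by 2.74 ± 0.26. Matrix remodelling genes rose in 10 of 13 cases and fell in 1, with a median of 4.58 (camera adjusted p = 1.16e-06 with BH, adjusted p = 0.163 with an estimated correlation). The heme-degrading enzyme Hmox1 (2.79 ± 0.19) and the glutathione reductase Gsr (2.82 ± 0.25) rose among 8 of 10 NRF2 targets, with 1 lower (camera adjusted p = 2.08e-04 with BH, adjusted p = 0.175 with an estimated correlation). Pkm (1.85 ± 0.14) and Gapdh (1.46 ± 0.13) rose among 11 of 15 glycolysis genes, with 2 lower (camera adjusted p = 2.89e-05 with BH, adjusted p = 0.318 with an estimated correlation). Cd36 rose by 1.09 ± 0.16. All 32 ribosomal protein genes rose, with a median of 1.09 (camera adjusted p = 9.54e-23 with BH, adjusted p = 0.175 with an estimated correlation). Adjusted over the list alone the counts were unchanged for these lists except the inflammatory one, where 12 rose.

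Among the receptors themselves, Rxra (-0.71 ± 0.11) and Rxrb (-0.76 ± 0.10) fell with stroke, while their partner receptors Rara (3.85 ± 0.40), Pparg (0.577 to 5.14 CPM) and Nr1h3 (2.90 ± 0.47) rose. The list of 11, with 6 higher and 2 lower (6 and 2 when adjusted over the list alone), did not pass camera (adjusted p = 0.447 with BH). The genes with the largest rises by rule were near 0 without stroke: Rhov, B3gnt5, Htr7 and Cxcl3 had no counts in aged vehicle and 19.6, 19.3, 11.3 and 15.0 CPM after stroke. Emp1 went from 0.162 to 123 CPM, Vcan from 0.185 to 42.6 CPM and Fanci from 0.0320 to 12.1 CPM. The largest falls by rule included Tmem204 (-3.36 ± 0.37), Gprasp2 (-2.91 ± 0.25) and the GTPase Gimap6 (-2.64 ± 0.25). Neutrophil markers S100a8 (2.48 ± 0.91) and S100a9 were called without passing as a list (camera adjusted p = 0.618 with BH). S100a8, S100a9, Dnaja1, Hspa1b, Nkg7, Gzma, Ccl8, Gfap and Ntsr2 lost their calls without at least 1 library, and limma voom called neither S100a9 nor Nkg7.

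The authors' deposited table for young bexarotene holds 197 genes, 127 higher and 70 lower, and 75 of the 79 genes called here are in it. The authors' deposited table for aged bexarotene holds 149 genes, 122 higher and 27 lower, and all 40 called here. The authors' deposited table for bexarotene after stroke holds 96 genes and all 9 called here. With 43 higher and 53 lower, the authors' deposited table after stroke has the opposite balance to the 8 higher and 1 lower called here. The balance here depended on the setting, with 38 higher and 21 lower by DESeq2 and 134 and 285 without a filter. The authors' deposited table for age holds 448 distinct genes, 291 higher and 157 lower, among them 224 of the 264 called here. In each of these tables every gene tested here had the same direction.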

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

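None of the tests in this part was chosen after its result was seen. Gene lists are given here because their bexarotene effect differed between groups of mice by a test of the difference itself, camera with BH adjustment at the preset correlation. With an estimated correlation none of the 25 differences passed, and the lowest adjusted p was 0.202. No explanation was tested for any of them.

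Between aged and young mice, bexarotene effects (aged minus young, median log2 difference over each list) were more positive for neutrophil markers (1.92), markers of infiltrating monocytes and macrophages (1.10), oligodendrocyte precursor markers (2.38), erythroid markers (1.78), inflammatory genes (0.36) and immediate early genes (0.23). They were more negative for interferon response genes (-0.47, lower in 18 of 18 members), disease-associated microglial genes (-0.27), ribosomal protein genes (-0.12) and MHC class I genes (-0.0966). With an estimated correlation the adjusted p of these 10 lists was 0.707 to 0.876. Single genes called for this difference numbered 0 by edgeR, 0 by limma voom and 5 by DESeq2. Neutrophil S100a8 averaged 182 and 131 CPM in young vehicle and bexarotene libraries, and 80.0 and 260 CPM in the aged ones.

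Between aged mice with and without stroke (stroke minus no stroke), the bexarotene effect was more negative for ependymal and choroid plexus markers (-1.61), T and NK cell markers (-0.94), infiltrating monocyte and macrophage markers (-0.80), neutrophil markers (-0.80), immediate early genes (-0.64), border-associated macrophage markers (-0.52) and PPAR-RXR targets (-0.23). It was more positive for heat shock genes (0.51), disease-associated microglial genes (0.33), genes of endoplasmic reticulum and amino acid stress (0.28), mitochondrially encoded genes (0.23), ribosomal protein genes (0.21), glycolysis genes (0.18), lysosomal genes (0.13) and MHC class I genes (0.0619). For these 15 lists the adjusted p with an estimated correlation was 0.202 to 0.572, lowest for the border-associated macrophage markers. Both differences use the aged vehicle and aged bexarotene libraries, with opposite signs. Opposite values of the same list in both, as for neutrophil markers, are therefore not independent results.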

How the results depend on the processing

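The choroid plexus covariate, the choroid plexus and neutrophil covariates together, and the removal of all libraries numbered 1 were chosen after seeing the data. Counts of changed genes are compared with 264 for age, 79, 40 and 9 for bexarotene in young, aged and aged stroke mice, 7497 for stroke, 0 for both differences of the bexarotene effect and 2 for age-changed genes moved back. RLE scaling gave 24 for aged bexarotene and 1 moved back. Without a filter 31653 genes were tested. The counts were then 677 for age, 457, 339 and 419 for bexarotene, 138 and 256 for its differences and 111 moved back. By direction bexarotene then gave 226 higher and 231 lower in young, 237 and 102 in aged and 134 and 285 in aged stroke mice. DESeq2 gave 519 for age, 210, 97 and 59 for bexarotene, 5 and 9 for its differences and 10 moved back, with 38 higher and 21 lower for aged stroke bexarotene. Limma voom gave 427 for age and 181 for young bexarotene. In simulated counts for aged bexarotene, false calls were 12 of 131 by DESeq2 (9.16%). They were 1 of 102 by voom (0.980%) and 2 of 106 by edgeR (1.89%). For edgeR they were 2.17% for age, 5.94% for young and 3.74% for aged stroke bexarotene, and 9.84% for stroke. For the differences of the bexarotene effect they were 2.67% and 0%. DESeq2 and voom were run on the aged bexarotene counts alone, and all counts were drawn from edgeR's own fit. Each comparison had a single draw, so these shares come without a measure of their error. Fitting only the groups compared gave 36 for young and 5 for aged stroke bexarotene and 1 moved back. The choroid plexus and neutrophil covariates gave 9 for aged and 14 for aged stroke bexarotene and 0 moved back. Removing the libraries numbered 1, which leaves fewer samples, gave 107 for age and 17, 26 and 3 for bexarotene. For the other settings the cause was not tested.

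Leaving out each library in turn gave 126 to 255 for age, 27 to 70, 9 to 35 and 1 to 17 for bexarotene in young, aged and aged stroke mice, 6432 to 7066 for stroke, 0 to 1 and 0 to 0 for the differences and 0 to 4 moved back. Of 227 called values of named genes, 165 kept their call in every alternative, 62 lost it in at least 1 alternative, 43 of them without 1 library, and 0 reversed. Of 68 list results, 67 kept their side of the threshold with RLE scaling, 65 with the replicate block, 52 with both covariates and 12 with an estimated correlation.

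The replicate block gave 20 for aged stroke bexarotene against 9, 88 for young bexarotene against 79 with 72 in common, and moved no other count by over 1.5 times. Among named genes and lists it changed no call in young bexarotene beyond those given with that comparison. For the other comparisons the numbers did not pair the libraries (lowest correlation -0.01 for age, -0.06 for aged bexarotene, -0.11 for aged stroke bexarotene and 0.03 for stroke), although 14 of 18 libraries correlated best with one of their own number. Scaling moved the median of all genes by less than 0.03. Depth limits genes near the floor of 0.396 CPM. At 1.5-fold, 13.4% of simulated changes were recovered for age and 4.48% for the stroke difference, and whether depth or the spread between libraries sets this was not tested.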

Other observations

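The tests of choroid plexus transcripts in this part were chosen after the result was seen, the others before, and the criterion for reading the starting level and dilution tests was made stricter after their results were seen. Stroke moved gene groups not yet described. Of 19 oxidative phosphorylation genes 18 rose with a median of 0.72, among them Cox5a (1.38 ± 0.13 SE, n = 3 libraries per group). Camera passed at the preset correlation (camera adjusted p = 4.33e-07 with BH, adjusted p = 0.318 with an estimated correlation). MHC class I presentation rose in 8 of 11 genes, including the peptide transporter Tap1 (1.69 ± 0.11; camera adjusted p = 3.79e-04 with BH, adjusted p = 0.228 with an estimated correlation). The lipid droplet coat gene Plin2 rose by 3.33 ± 0.27 among 9 of 16 PPAR-RXR targets, with Acadm lower (-0.70 ± 0.08; camera adjusted p = 0.0466 with BH, adjusted p = 0.465 with an estimated correlation). Immediate early genes, which tissue dissociation also induces, rose in 11 of 13 cases, including Fos (2.95 ± 0.47; camera adjusted p = 8.21e-04 with BH, adjusted p = 0.465 with an estimated correlation). Phagocytosis genes went both ways, 7 higher and 7 lower of 18, with the scavenger receptor Msr1 at 3.55 ± 0.19 and the engulfment adaptor Elmo1 at -1.19 ± 0.08. Their median (0.25) and mean (0.24) were above 0 while the direction of the test was down (camera adjusted p = 0.964 with BH). Complement genes rose in 8 of 13 cases and fell in 4, with Cfp at 4.01 ± 0.22. Of 17 cholesterol synthesis genes 10 rose, and neither list passed camera (both adjusted p = 0.0957 with BH). Adjusted over the list alone, the counts of all these lists were unchanged.

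In aged vehicle cells, lysosomal genes had a median of 0.16 with none of 18 called by edgeR (6 when adjusted over the list alone; camera adjusted p = 9.46e-04 with BH, adjusted p = 0.497 with an estimated correlation). DESeq2 and limma voom called Ctsb, Ctss and Ctsz higher. Senescence genes had a median of 0.59 with none of 8 called by edgeR (2 when adjusted over the list alone; camera adjusted p = 0.00712 with BH, adjusted p = 0.111 with an estimated correlation). DESeq2 called Cdkn1a and Ccl8, limma voom Cdkn1a, and edgeR both without the libraries numbered 1, a setting chosen after seeing the data. The hypoxia list held 1 called gene, the oxygen sensor Egln3 (0.831 to 3.88 CPM, not called without the libraries numbered 1; 2 when adjusted over the list alone; camera adjusted p = 0.00279 with BH, adjusted p = 0.0649 with an estimated correlation). Inflammatory genes had a median of 0.05 and a mean of -0.15, with the test above 0 and 2 of 17 called, 1 without the libraries numbered 1 (2 when adjusted over the list alone; camera adjusted p = 0.0273 with BH, adjusted p = 0.425 with an estimated correlation). Heat shock, mitochondrially encoded, oxidative phosphorylation, amino acid stress and B cell lists also passed only at the preset correlation, with medians of 0.50, 0.28, 0.10, 0.34 and 1.09. Their adjusted p with an estimated correlation was 0.523, 0.523, 0.523, 0.425 and 0.185. Heat shock Hspa1b was at 98.1, 67.8 and 51.1 CPM in young and at 29.5, 142 and 377 CPM in aged vehicle libraries. Rxrg, a further RXR gene that was chosen after its values were seen, rose from 0.209 to 9.64 CPM.

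Further lists passed camera with bexarotene at the preset correlation alone, given as median log2 fold changes. In young mice they were homeostatic (-0.08) and phagocytosis genes (0.07; adjusted p = 0.827 and adjusted p = 0.112 with an estimated correlation, camera with BH). In aged mice they were matrix remodelling (-0.48), amino acid stress (-0.19), interferon response (-0.17), ribosomal protein (-0.08) and phagocytosis genes (0.02), with an adjusted p of 0.101 to 0.927 with an estimated correlation. After stroke they were T and NK cell (-0.77) and endothelial markers (-0.24), immediate early (-0.29), mitochondrially encoded (0.16), ribosomal protein (0.12), lysosomal (0.11) and cell cycle genes (0.20), with an adjusted p of 0.522 to 0.693 with an estimated correlation. By edgeR the phagocytosis list held 1 called gene in young and 1 in aged mice (1 and 3 when adjusted over the list alone). At both ages it was Abca1, already counted among the LXR-RXR targets, and the other lists held none. DESeq2 also called the homeostatic gene Mef2c lower in young mice and the matrix gene Mmp12 lower in aged mice. Adjusted over the list alone there were 2 lower homeostatic genes in young mice, 1 lower matrix gene in aged mice, and 1 lower endothelial marker and 1 lower immediate early gene after stroke.

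Genes that differ between aged and young mice may include some that differ between mouse stocks, and the labels do not say whether both ages came from 1 source. Called genes lay within 5 genes of one another in 34 pairs, against a median of 21 and a highest of 45 in 10000 random draws (permutation p = 0.00950, one-sided, 252 of 264 genes placed), as a stock difference would give. Paralogs were left out only by the first letters of their symbols, so gene clusters such as Clec7a with Olr1 and Klrd1, chosen after their values were seen, add to the pairs. Ch25h and its neighbours Ifit2 and Ifit3, also chosen after their values were seen, all rose (3.03, 1.56 and 1.69). Neighbours that respond together or share reads would give such pairs without a stock difference, and the random draws do not allow for them. Nnt, which is partly deleted in 1 substrain, was at 2.11 and 1.47 CPM, and its log2 fold change of -0.53 (95% interval -1.87 to 0.82) is too wide to tell. The interferon, MHC class I and disease-associated lists, known from aged microglia, rose in 3 of 3 cases, which is consistent with age, so age and stock both stay open.

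Over the 65 genes that rose in young mice the median bexarotene effect was 0.64 in aged and 0.39 in aged stroke mice, and the effect was smaller with than without stroke in 51 of 65. The difference itself passed limma's rotation test fry over those genes (p = 0.00316, model over n = 18 libraries, 3 per group). That model gives each gene 1 spread for all groups. The chi-square per degree of freedom between replicates was 22.5 to 41.8 with stroke and 6.19 to 17.6 without, at unlike depth. The test therefore cannot decide whether a larger spread between stroke libraries plays a part, and this stays open. A higher starting level after stroke stays open. Among 32 genes not raised by stroke the median difference was -0.11, against -0.23 over all 65 genes. The 95% bootstrap interval over the 32 genes was -0.201 to -0.0181, which leaves out the variation between libraries. The median of the 32 genes lay below 0 but short of the fall set in advance for arguing against this cause. These genes were picked with vehicle libraries that also enter the difference, which pushes it upwards. Dilution by incoming cells that do not respond stays open too, with a median difference of -0.0113 (-0.344 to 0.0978) among only 6 genes that stroke lowered. They were picked with the same vehicle libraries. A biological change in RXR response after stroke was not tested, and for the difference in single genes edgeR called 0, limma voom 0 and DESeq2 9, Abcg1 among them.

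Choroid plexus transcripts differed between libraries of 1 group, with Ttr at 1481, 109 and 384 CPM in aged vehicle. RNA of choroid plexus tissue carried along despite CD11b selection is a candidate source, since within groups Ttr deviated with the mean of 4 other markers over 18 libraries (r = 0.994, rho = 0.998, permutation p = 3.0e-05 for each, the 1 relation tested, r = 0.995 without the 2 farthest libraries), and Enpp2 reached 1148 CPM. Handling shared by libraries of 1 number may add, as the library numbered 1 was highest in Ttr in 5 of 6 groups (exact binomial p = 0.0178, one-sided). Number 1 was picked after its values were seen, so this p is too small. What the numbers mark is not given in the sources used here, and no biological explanation was tested.

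Splits of the same libraries into groups of 3 number 10 per comparison, the real one included, too few for a share under 0.05. Every other split mixes the real groups, so a strong real difference enters the spread within its groups and keeps its count low. The real value and the highest of the other splits were 264 and 1 for age, 79 and 1 for young bexarotene, 40 and 0 for aged bexarotene, 7497 and 0 for stroke and 2 and 0 for genes moved back, so 1 split, the real one, was as large in each. In young bexarotene the splits that part all 3 same-numbered pairs gave 0, and those that part 1 pair gave 0 or 1. For bexarotene after stroke the real split gave 9 and another gave 18, so 2 of 10 were as large. That split set aged stroke bexarotene libraries 1 and 3 with aged stroke vehicle library 2. For the differences of the bexarotene effect the real count was 0, so all 25 of 25 splits drawn, the real one included, were as large, which a count of 0 fixes beforehand, and the splits say nothing of chance here. The highest counts among them were 14 for age and 15 for stroke.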
